A study of Mus musculus with 20 samples.

How the data were processed

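RNA from MIN6 cells, a mouse pancreatic beta cell line, was measured on 20 Affymetrix mouse expression arrays with 22690 probe sets each. The deposited table gives 1 value per probe set and array on the log2 scale. Per the submitters' processing notes, the authors made these values with RMA, a method that corrects background, normalizes and summarises the probes of a probe set, in affy 1.12.2 under R 2.4.0. Whether all arrays went through a single RMA run was not stated in what was read here. Scanner descriptions of 18 arrays were read only for the scan day, coded day 1 to day 4, and for the chip lot, of which there was 1. They hold no measurements. For the remaining 2 arrays (22.7 mM glucose with 1 µM amylin for 12 h, and 5.5 mM glucose with 10 µM amylin for 24 h) no scanner description was used here. Arrays give no counts, so their number limits the precision.

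The 64 control probe sets were left out of the gene tables and used as measures of array quality. These measures were the signal of the 3′ minus that of the 5′ probe sets for actin and Gapdh, which is larger where RNA is degraded or incompletely copied, the 18S probe set and the spiked BioB and Cre controls. Of the probe sets, 20380 were listed with exactly 1 gene, 691 with several and 1606 with none, and only the first kind was used. Each of 12393 genes was represented by its probe set of highest mean over the 20 arrays. The 40% of genes with the lowest mean (below 7.08 on the log2 scale) were left out, and 7436 genes were tested. Ins1 was not analysed here.

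Differences were fitted with limma 3.58.1 (lmFit, then eBayes with trend=TRUE) in R 4.3.3, and p-values were adjusted over the 7436 genes by the Benjamini-Hochberg method at 0.05. No condition was arrayed more than once. The fit therefore had a term for glucose and a factor for the 10 amylin conditions, with 9 residual degrees of freedom, so that the error was the spread of the glucose differences between matched conditions. The contrasts were 22.7 minus 5.5 mM glucose (10 matched pairs), the mean of the 9 treated conditions minus untreated, 24 minus 2 h and 12 minus 2 h, 20 minus 1 µM and 10 minus 1 µM (6 matched pairs each), and the change with dose at 24 h minus that at 2 h. Differences between glucose levels in the effects of amylin, time and dose were tested in a fit with glucose crossed with treatment, dose and time, with 8 residual degrees of freedom. Single conditions were not tested and are given as the log2 difference from the untreated array of the same glucose level.

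A set of 24 gene lists was fixed before the data were examined, as were the contrasts, the filters and the rule for named genes. The lists cover ER chaperones and ER-associated degradation, the integrated stress response, cytosolic heat shock proteins, the proteasome, the ubiquitin system, beta cell identity and secretion, glycolysis, ChREBP and lipogenic genes, cholesterol synthesis, oxidative phosphorylation, immediate early genes, NF-kB and chemokines, the interferon response, oxidative stress and metallothioneins, apoptosis and p53 targets, DNA replication, mitosis, hypoxia, amyloid and amylin receptor genes, and markers of other islet hormones, acinar, duct, fibroblast, and immune and endothelial cells. The 20 lists with at least 5 tested members were tested with camera of limma at its preset correlation of 0.01 between genes, adjusted over the 20 lists, and again with an estimated correlation and with fry (statmod 1.5.0). A list's score in an array is the median deviation of its members from their means over the arrays. Scores were compared between matched pairs with exact 2-sided permutation tests that flip the signs of the pair differences. Relations of scores to RNA quality used 100000 permutations.

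Genes were named by a rule: for the contrasts of glucose, amylin, 24 minus 2 h and 20 minus 1 µM, the 10 highest and the 10 lowest log2 differences among genes with adjusted p under 0.05 and the same sign in every matched pair (for amylin, in both glucose levels). Where fewer than 5 passed in a direction, the 5 of smallest p were named as not passing. Up to 4 members of each list with the smallest p were added, and Ins1, Ins2, Iapp, Pdx1, Txnip, Hspa5 and Ddit3 were always considered. For the other contrasts the 5 of smallest p in each direction were named. Clone-type symbols were counted and not named.

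Alternatives were no filter, a filter on the lowest 60%, the arrays centred on their medians or quantile normalized again, the mean of all probe sets of a gene, eBayes without trend or with robust estimation, an unmatched or an additive model, the 18 treated arrays alone, scan day as a block, the 2 arrays without a scanner description left out, and each array left out in turn. Array weights, the 3′ minus 5′ signal as a covariate, scan day in the additive model and, for gene lists, the array of 22.7 mM, 1 µM and 2 h left out were added after the data were seen. Fits with scan day used only the arrays with a known scan day, so they also left out the 2 arrays without a scanner description. The steps were also tested on simulated data with 200 changed genes among 7436. At a true log2 difference of 0.5 they recovered 89.6% of the changed genes for glucose, 79.1% for 24 minus 2 h, 65.7% for 20 minus 1 µM and 41.8% for amylin minus none. At a true difference of 1 they recovered 95.5% or more. Each comparison had 6 to 10 false calls over all simulated sizes together. The simulated noise was independent between genes and arrays, with no deviating array and no RNA quality difference tied to glucose. These rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.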

Results

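Gene expression was measured in MIN6 cells, a mouse line of insulin-secreting pancreatic beta cells, grown at 22.7 or 5.5 mM glucose and exposed to amylin, the peptide hormone that beta cells release with insulin and that forms amyloid in human islets. At each glucose level, 1 array came from untreated cells and 9 came from cells given 1, 10 or 20 µM amylin for 2, 12 or 24 h, which makes 10 arrays per level and 20 in all. No condition was arrayed more than once, so the number of arrays limits the precision, and the p-values below measure the spread between these 20 arrays rather than between replicate cultures. Log2 values of 7436 genes were compared.

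The arrays differed in quality in 2 ways. First, the actin 3′ minus 5′ signal, a measure of RNA quality, averaged 1.83 at 22.7 mM and 1.22 at 5.5 mM glucose, and it was higher at 22.7 mM in 10 of 10 matched pairs (mean difference 0.604, exact permutation p = 0.00195, the smallest possible). The same signal for Gapdh averaged 1.40 and 0.947, higher in 9 of 10 pairs (exact permutation p = 0.00391). RNA quality therefore moved with glucose. Second, the 2 arrays without a scanner description had medians of 7.25 and 7.28 against 7.04 to 7.15 in the other 18, and mean correlations with the other arrays of 0.941 and 0.920 against 0.969 to 0.978. These 2 arrays were those of 22.7 mM glucose with 1 µM amylin for 12 h and of 5.5 mM glucose with 10 µM amylin for 24 h.

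**Figure D1:**
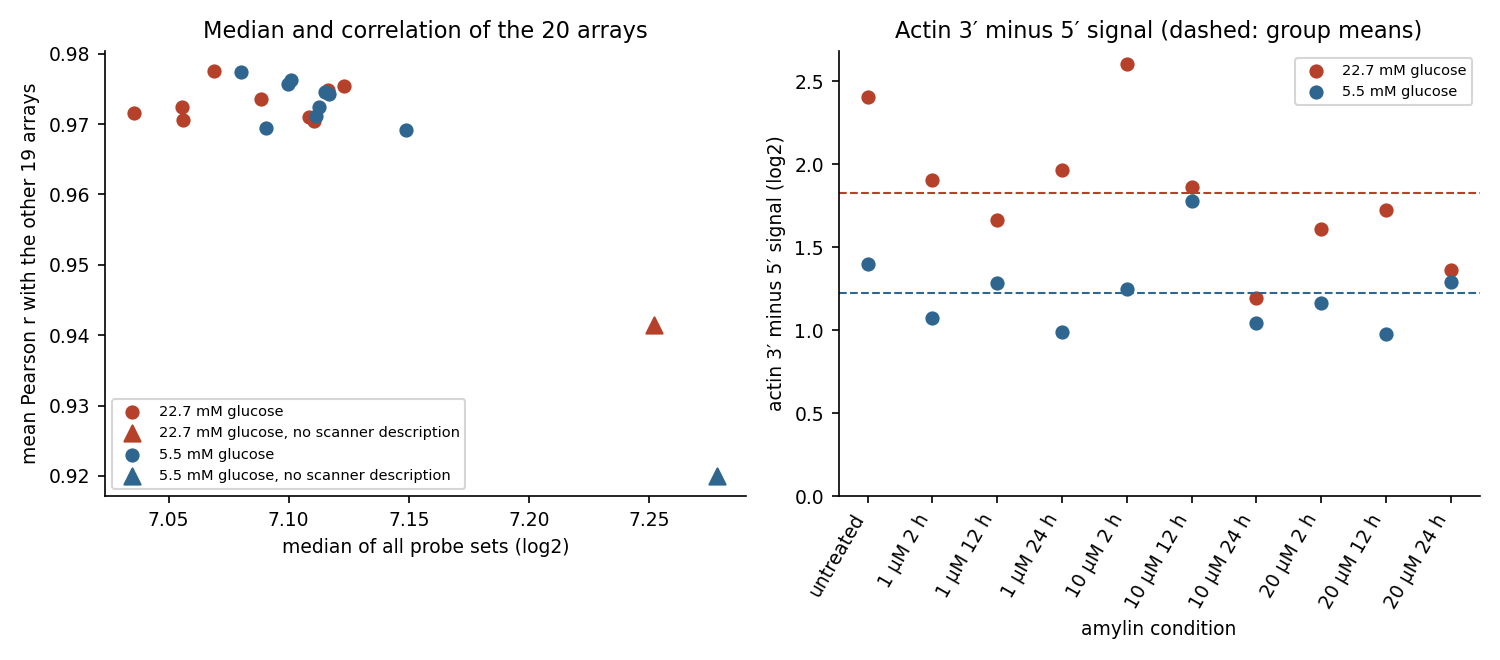
Left, the median of all probe sets (log2) of each of the 20 arrays against its mean Pearson r with the other arrays, coloured by glucose level, where the 2 arrays without a scanner description (triangles) lie apart at r of 0.941 and 0.920. Right, the actin 3′ minus 5′ signal (log2) of each array by amylin condition, with dashed group means of 1.83 at 22.7 mM and 1.22 at 5.5 mM glucose.

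The comparison of 22.7 with 5.5 mM glucose asked which genes differ with the glucose level across all amylin conditions. Fxyd6, which encodes a regulator of the sodium pump, rose most at 22.7 mM, by 1.11 on the log2 scale (SE 0.16, 10 pairs, 2.16-fold). Fam151a rose by 0.98 (SE 0.16), and Txnip, a thioredoxin-binding protein gene induced by glucose through ChREBP, by 0.97 (SE 0.23, adjusted p = 0.0267, 9 of 10 pairs). The largest decreases were those of Map1b, a microtubule-associated protein gene, at −0.87 (SE 0.11), and of Trim35 at −0.85 (SE 0.12). Pdia3, a gene of protein folding in the endoplasmic reticulum (ER), fell by 0.71 (SE 0.13) and Trib3, of the integrated stress response, by 0.81 (SE 0.19).

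Other genes that rose in all 10 pairs were St6gal1 (0.63), Npepl1 (0.56), Spock2 (0.56), Prrt1 (0.55), Clu (0.51), Tmem98 (0.50), Serpina1b (0.47) and Vat1 (0.46). Clu encodes the secreted chaperone clusterin, and St6gal1 a sialyltransferase of the Golgi. Genes that fell in all 10 pairs were Ralgapa1 (−0.80), Ifrd1 (−0.64), Sst (−0.64), Rbm18 (−0.62), Mgat2 (−0.60), Rnf4 (−0.57), Zfp445 (−0.55) and Lin7c (−0.54). Sst encodes the hormone somatostatin. A second probe set of Clu, Serpina1b, Trib3 and Lin7c moved the same way as the one used. Weaker probe sets of St6gal1, Spock2, Prrt1, Map1b, Rbm18, Rnf4 and Txnip differed by only −0.12 to 0.09.

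**Figure D2:**
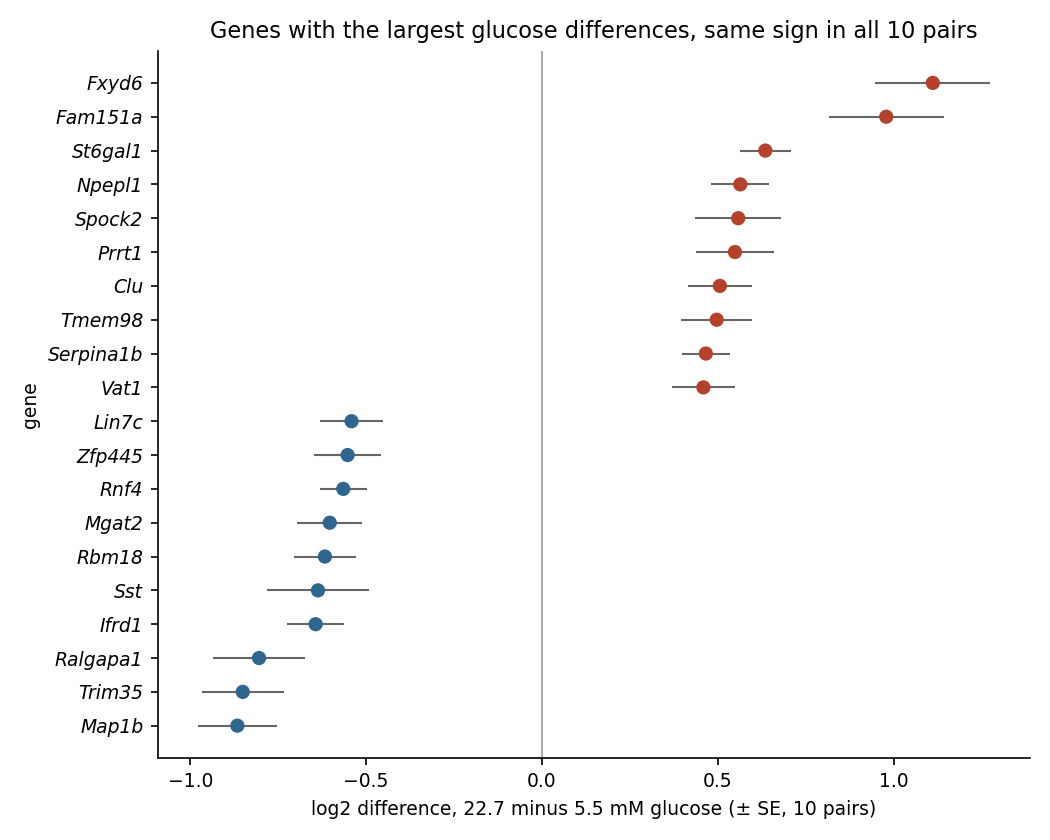
Log2 difference between 22.7 and 5.5 mM glucose (horizontal axis, points with SE over 10 matched pairs) for the 10 genes with the highest and the 10 with the lowest difference among those with limma adjusted p under 0.05 and the same sign in all 10 pairs. The differences run from 1.11 for Fxyd6 to −0.87 for Map1b.

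In the list of ER chaperones and ER-associated degradation, 9 of 28 genes fell and none rose, and 17 passed when adjusted over the list alone. Dnajc3 (−0.59), Pdia3 (−0.71), Pdia6 (−0.40) and Dnajb11 (−0.38) were among them, while Hspa5, the chaperone BiP, did not pass (−0.40, adjusted p = 0.0988). The list's median difference was −0.28 (camera adjusted p = 1.51e-12, and adjusted p = 0.366 with an estimated correlation). Its score was lower at 22.7 mM in 9 of 10 pairs, with means of −0.099 (SD 0.0887) at 22.7 mM and 0.113 (SD 0.178) at 5.5 mM (exact permutation p = 0.0176, adjusted p = 0.196 over 20 lists). In the integrated stress response list all 25 differences were negative, 5 genes fell, and 12 passed when adjusted over the list alone. Psat1 (−0.58), Trib3 (−0.81), Atf4 (−0.36), the transcription factor that heads this response, and Nupr1 (−0.77) fell, whereas Ddit3, which encodes CHOP, did not pass (−0.52, adjusted p = 0.0612). The list's median was −0.23, lower in 8 of 10 pairs (camera adjusted p = 1.51e-12, and adjusted p = 0.473 with an estimated correlation).

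Within single scan days the score differences (22.7 minus 5.5 mM) were −0.321 on day 2, −0.346 on day 3 and −0.0879 on day 4 for the ER list. For the integrated stress response list they were −0.347, −0.112 and −0.563. Day 2 held 1 array at 22.7 and 3 at 5.5 mM, day 3 held 4 and 3, day 4 held 4 and 2, and day 1 held a single array. The arrays of a day were not matched on amylin condition, so these differences mix glucose with dose and time. On day 3 the arrays at 22.7 mM were untreated or at 2 or 24 h, and those at 5.5 mM at 12 or 24 h. The 5.5 mM arrays of day 2 included the untreated array, whose integrated stress response score was the highest of all arrays (0.51). Without the 2 arrays that had no scanner description, the exact permutation p over 8 pairs was 0.00781 for the ER list (mean difference −0.24) and 0.0547 for the integrated stress response list (−0.30). With the 3′ minus 5′ signal as a covariate the ER difference went from −0.212 (SE 0.067) to −0.070 (SE 0.121). That of the integrated stress response went from −0.267 (SE 0.100) to −0.200 (SE 0.199). RNA quality and glucose can therefore not be told apart for these lists.

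Camera called 2 further lists. Of 34 proteasome genes, Psma7 (−0.40, 10 of 10 pairs) and Psma4 (−0.43) fell, and the same number passed when adjusted over the list alone. The proteasome median was −0.065, negative in 21 genes (adjusted p = 8.54e-04, and adjusted p = 0.811 with an estimated correlation). All 11 glycolysis genes had positive differences, with a median of 0.17, and Aldoc (0.35) and Pfkm (0.26) rose, with 4 passing when adjusted over the list alone (camera adjusted p = 0.00592, and adjusted p = 0.811 with an estimated correlation). The glycolysis score was higher at 22.7 mM in 8 of 10 pairs (exact permutation p = 0.0391, adjusted p = 0.196), and the exact permutation p was 0.109 without the 2 deviating arrays. Within days 2, 3 and 4 the proteasome score differed by −0.155, −0.128 and −0.0648, and the glycolysis score by 0.0252, 0.183 and 0.252. These differences were not matched on amylin condition either. With the 3′ minus 5′ signal as a covariate the proteasome difference went from −0.079 (SE 0.047) to −0.031 (SE 0.092). That of glycolysis went from 0.202 (SE 0.079) to 0.317 (SE 0.152).

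**Figure D3:**
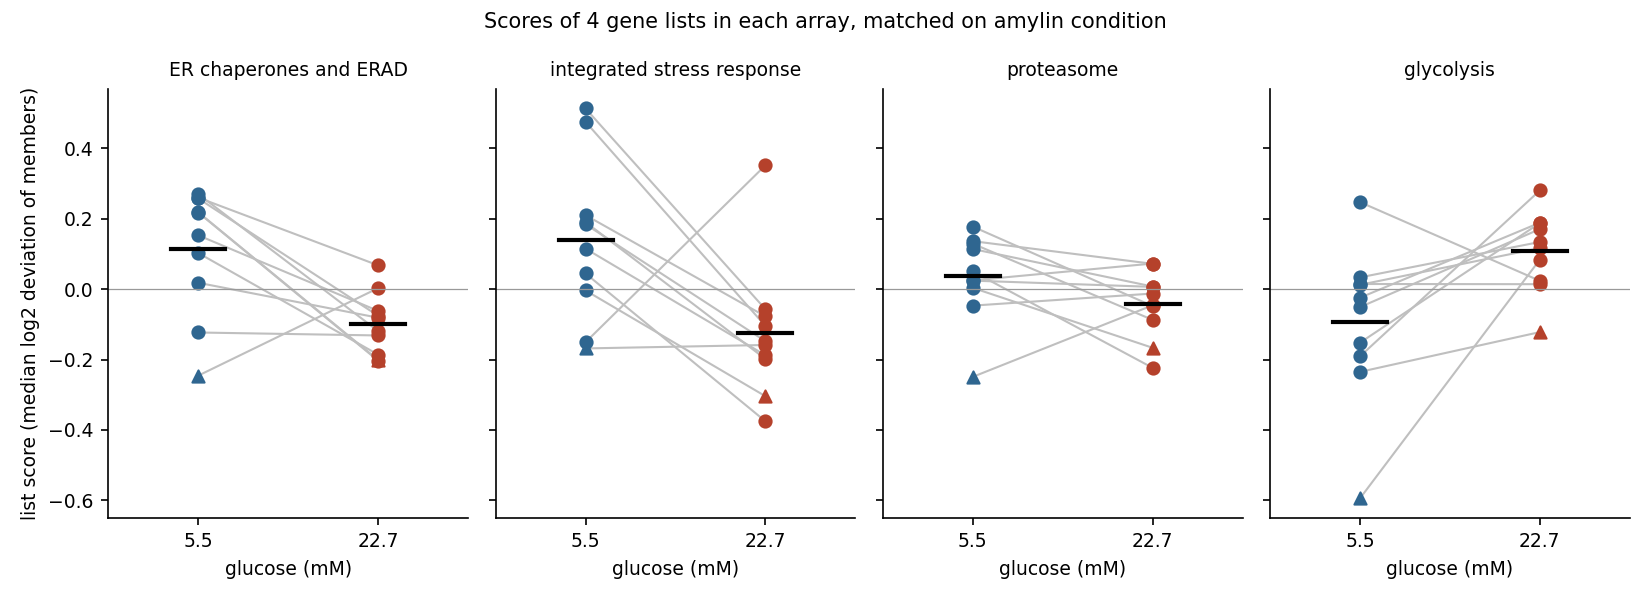
Scores (median log2 deviation of the members from their means, vertical axis) of 4 gene lists in each array at 5.5 and 22.7 mM glucose, with lines joining arrays of the same amylin condition and triangles for the 2 arrays without a scanner description. The ER chaperone score was lower at 22.7 mM in 9 of 10 pairs and the integrated stress response score in 8 of 10.

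Genes of the remaining lists moved singly, and camera adjusted p ranged from 0.266 to 0.862. Among 27 beta cell genes, the transcription factor genes Foxa2 (0.31) and Nkx2-2 (0.33) rose and Glp1r, the incretin receptor gene, fell (−0.43, but 0.091 with SE 0.143 once the 3′ minus 5′ signal was a covariate). Adjusted over the list alone, 4 rose and 2 fell. Ins2 (−0.10, adjusted p = 0.145), Iapp, the mouse amylin gene (−0.12, adjusted p = 0.135), and the transcription factor gene Pdx1 (0.13, adjusted p = 0.322) did not pass. Both metallothionein genes Mt1 (0.46) and Mt2 (0.46) rose and Srxn1 fell (−0.44) among 13 oxidative stress genes, with 3 rising and 2 falling when adjusted over the list alone. Of 15 ChREBP and lipogenic genes, Elovl6 (0.29) and Txnip rose, and adjusted over the list alone 3 rose and 1 fell. Ufd1 (−0.33), Uba3 (−0.49) and Sqstm1 (−0.32) fell among 21 ubiquitin genes, with 1 higher and 3 lower when adjusted over the list alone, and with the same covariate Uba3 was at 0.050 (SE 0.155). Mcm7 (0.30) and Ccne1 (0.38) rose and Rfc3 (−0.33) fell among 23 DNA replication genes, with 4 higher and 1 lower when adjusted over the list alone.

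Mcl1 (0.29) and Sesn1 (0.34) rose among 16 apoptosis and p53 genes (3 higher and 2 lower adjusted over the list alone). A single gene passed in each of the lists of heat shock proteins (Hspa9, −0.53, of 18), cholesterol synthesis (Lss, 0.23, of 18), oxidative phosphorylation (Ndufb9, −0.22, of 40) and amyloid and amylin receptor genes (Clu, of 10). Adjusted over the list alone, these lists had 1, 1, 0 and 2 genes. The amyloid score was higher at 22.7 mM in 9 of 10 pairs (mean difference 0.10, exact permutation p = 0.0312, adjusted p = 0.196). None passed among 16 immediate early, 8 NF-kB, 9 interferon, 23 mitosis, 10 hypoxia and 5 fibroblast genes, and adjusted over the list alone only interferon genes did, 2 higher and 1 lower. The medians of the heat shock, ubiquitin, cholesterol, oxidative phosphorylation, NF-kB and oxidative stress lists were positive while camera, which called none of them, ranked them downward. Among lists too small for camera, Sst of 3 other islet hormone genes fell and Krt18 (0.35) of 4 duct genes rose, while 2 acinar genes and 1 immune gene did not pass.

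In all, limma called 408 of 7436 genes at adjusted p under 0.05, 270 higher and 138 lower at 22.7 mM. Of these 151 had the same sign in all 10 pairs, 28 differed by at least 0.58 on the log2 scale, and 1 had a clone-type symbol. Without the 2 deviating arrays 743 passed, and 1090 with scan day as a block in the same remaining arrays. Leaving out 1 array at a time gave 98 to 657. With the 3′ minus 5′ signal as a covariate none passed (1326 at unadjusted p under 0.05), and the median SE of the 408 genes grew from 0.0777 to 0.142 while 396 kept their sign.

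The comparison of amylin with no treatment asked what the peptide changed on average over doses and times. Among the genes named by the rule, the lowest values after amylin were those of Id3, a gene of an inhibitor of differentiation (−0.94, SE 0.20), Egr1 (−0.92, SE 0.29) and Dusp1 (−0.74, SE 0.18). None passed adjustment (limma adjusted p of 0.776 or more). Shisa2 (−0.64), Snhg6 (−0.60) and Pcp4 (−0.46) were the others of smallest p among lower genes. Bbx (0.49), Scnn1a (0.41), Tes3-ps (0.36), Tbc1d20 (0.35) and Tysnd1 (0.33) were those among higher genes, and none of them passed. Ddit3 differed by −0.37, Txnip by −0.30, Hspa5 by −0.16, Pdx1 by −0.15, Iapp by −0.09 and Ins2 by −0.02.

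Immediate early genes, which signalling induces within minutes, had a median of −0.26 after amylin, negative in 13 of 16 genes (camera adjusted p = 0.00859, and adjusted p = 0.556 with an estimated correlation). Adjusted over the list alone, Dusp1, Egr1 and Ier2 (−0.46) passed. Integrated stress response genes had a median of −0.25, negative in 24 of 25 (adjusted p = 0.00111, and adjusted p = 0.875 with an estimated correlation), with Ppp1r15a and Ddit4 both at −0.38. The 5 tested fibroblast markers were all positive, with a median of 0.25, including Sparc (0.42) and Fn1 (0.29) (adjusted p = 2.97e-04, and adjusted p = 0.489 with an estimated correlation). Other markers of this list (Col1a1, Col3a1, Vim, Thy1, Pdgfrb, Lum and Dcn) lay below the expression filter and were not tested. The 2 deviating arrays, both treated, had fibroblast markers raised by 0.44 and 0.61, and the median was 0.18 without them. With no filter, acinar (0.20) and immune and endothelial markers (0.16) were higher after amylin as well. Interferon genes had a median of 0.13, positive in 6 of 9 (adjusted p = 0.0255, and adjusted p = 0.875 with an estimated correlation). Each of these values rests on 1 untreated array per glucose level. The immediate early score was highest of all arrays in the untreated array at 22.7 mM (0.46), and the integrated stress response score in the untreated array at 5.5 mM (0.51).

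By limma, 0 genes passed and 419 had an unadjusted p under 0.05, 95 higher and 324 lower, where 371.8 of 7436 were expected. Without the 2 deviating arrays 0 passed, and leaving out 1 array at a time gave 0 or 1.

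The comparison of 24 with 2 h of amylin asked what changed during exposure. Immediate early genes were lower at 24 h: Ier2 fell by 0.72 (SE 0.12, adjusted p = 0.0216), and Fos (−1.09), Egr1 (−1.07), Nr4a1 (−0.83) and Nr4a2 (−0.80) were also lower without passing. Of the 16 list members 14 were negative, 1 passed over all genes and 8 passed when adjusted over the list alone. The median was −0.31, and camera called the list with either correlation (adjusted p = 9.84e-10, and adjusted p = 0.0301 with an estimated correlation). Its score was lower in 6 of 6 pairs, with means of −0.191 at 24 h and 0.200 at 2 h (exact permutation p = 0.0312, the smallest possible, adjusted p = 0.312). Within scan day 3 the mean scores were 0.241 at 2 h, −0.156 at 12 h and −0.129 at 24 h (2 arrays each). Within day 4 they were 0.0566, −0.0236 and −0.107 (1, 2 and 3 arrays). Time and glucose are mixed within these days. On day 3 both 2 h arrays were at 22.7 mM and both 12 h arrays at 5.5 mM. On day 4 the single 2 h array was at 5.5 mM and both 12 h arrays at 22.7 mM. The 24 h arrays of each day came from both levels. Day 2 held treated arrays of 2 h only.

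Besides Ier2, 3 genes fell from 2 to 24 h, each in 6 of 6 pairs. They were Cirbp, which encodes a cold-inducible RNA-binding protein (−0.96, SE 0.15), the linker histone gene H1f2 (−0.70, SE 0.097) and Crybg3 (−0.58, SE 0.083). No gene rose. The higher genes of smallest p were Chordc1 (0.58, adjusted p = 0.0504), Dtx2 (0.56), Trmt1l (0.50), Banp (0.47) and Rnf112 (0.42), none of them passing. Ddit3, Hspa5, Iapp, Ins2, Pdx1 and Txnip differed by −0.13 to 0.05, and of these all but Pdx1 changed sign under some alternative processing.

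**Figure D4:**
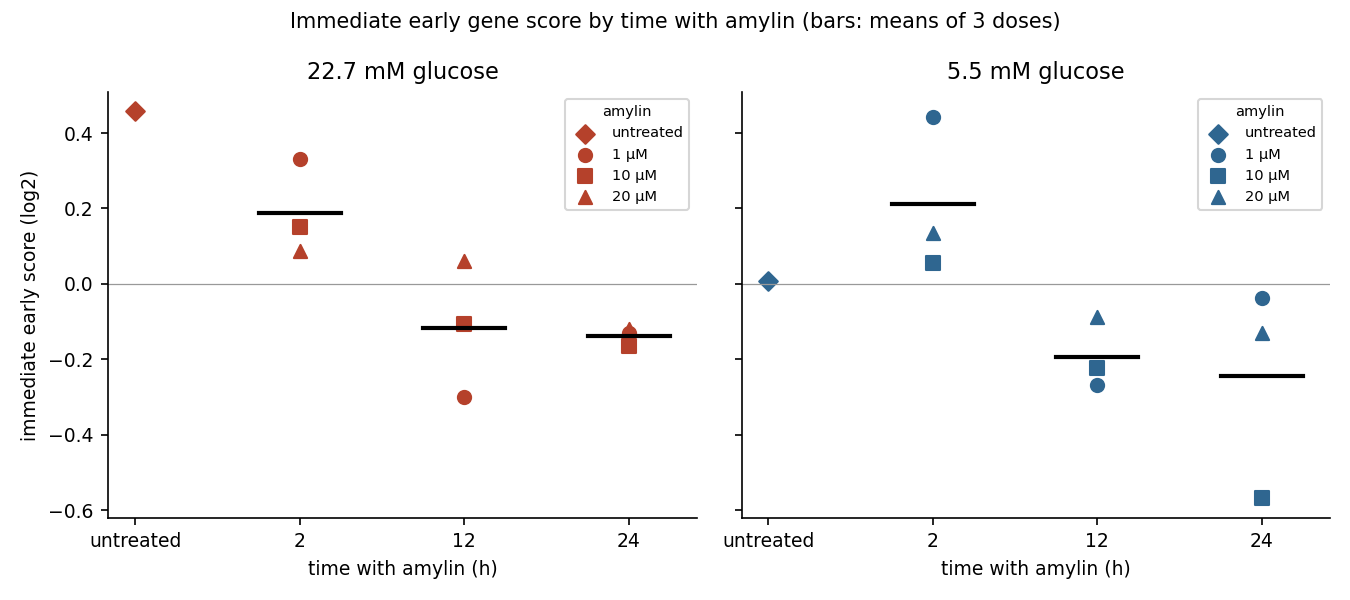
Immediate early gene score (log2, vertical axis) in each array against time with amylin (h), by glucose level, with symbols for dose and bars for the means of 3 doses. The score was lower at 24 h than at 2 h in 6 of 6 matched pairs, and the untreated arrays lie at 0.46 (22.7 mM) and 0.01 (5.5 mM).

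Camera called 5 further lists at 24 h, each with a lower median, and none held with an estimated correlation. Oxidative phosphorylation genes had a median of −0.10, negative in 32 of 40 (adjusted p = 9.32e-05, and adjusted p = 0.602 with an estimated correlation). The proteasome median was −0.10 (adjusted p = 0.00594, and adjusted p = 0.826 with an estimated correlation). The oxidative stress median was −0.11 (adjusted p = 0.0252, and adjusted p = 0.602 with an estimated correlation). Integrated stress response genes had a median of −0.11 (adjusted p = 0.047, and adjusted p = 0.852 with an estimated correlation). Glycolysis genes also had a median of −0.11, negative in 10 of 11 (adjusted p = 0.047, and adjusted p = 0.826 with an estimated correlation). Without the 2 deviating arrays only oxidative phosphorylation of these 5 was still called, with a median of −0.057, and the medians of the proteasome, oxidative stress, integrated stress response and glycolysis lists were −0.013, −0.077, −0.035 and −0.042. With scan day as a block only the integrated stress response was still called (−0.22), and the proteasome (0.010) and glycolysis (0.14) medians were positive. The integrated stress response call rests on 1 array, that of 22.7 mM, 1 µM and 2 h, without which its median was 0.020 (adjusted p = 0.112).

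Limma called 4 genes between 24 and 2 h, with 644 at an unadjusted p under 0.05, and 33 without the 2 deviating arrays. The count was 0 with the arrays centred on their medians and 0 to 143 with 1 array left out.

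Between 12 and 2 h, Abca1, which encodes a cholesterol exporter, fell by 0.87 (SE 0.12), and Cirbp (−0.92), H1f2 (−0.64), Crybg3 (−0.62) and Hs3st1 (−0.62) also fell. Trmt1l (0.71, SE 0.092), Khdc4 (0.64) and the cytochrome b5 gene Cyb5a (0.59) rose. All 8 had the same sign in 6 of 6 pairs, with adjusted p of 0.00385 to 0.0221. Chordc1 (0.57) and Dtx2 (0.55) did not pass. The immediate early median was −0.30 and camera again called the list with either correlation (adjusted p = 6.76e-09, and adjusted p = 0.0403 with an estimated correlation). No member passed over all genes and 7 passed when adjusted over the list alone, and the score was lower in 6 of 6 pairs (exact permutation p = 0.0312, adjusted p = 0.446). ER chaperone genes had a median of 0.12, positive in 25 of 28 (adjusted p = 0.00409, and adjusted p = 0.768 with an estimated correlation). Integrated stress response genes had a median of −0.079 (adjusted p = 0.0192, and adjusted p = 0.768 with an estimated correlation), but of 0.058 without the array of 22.7 mM, 1 µM and 2 h.

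Limma called 8 genes between 12 and 2 h, 3 higher and 5 lower, with 692 at an unadjusted p under 0.05. Without the 2 deviating arrays 55 passed, including these 8, and leaving out 1 array at a time gave 4 to 39. Across the 10 comparisons, the immediate early list at 24 and at 12 h was the only camera call to hold with an estimated correlation. Both comparisons subtract the same 2 h arrays. The repeated call, and the repeats of Cirbp, H1f2 and Crybg3, are therefore not independent.

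The comparison of 20 with 1 µM amylin asked for effects of dose. Proteasome genes were slightly higher at 20 µM, with a median of 0.092, positive in 28 of 34 (camera adjusted p = 6.32e-05, and adjusted p = 0.692 with an estimated correlation), including Psmd13 (0.27), Psmc1 (0.22), Psma7 (0.21) and Psmd2 (0.20). Mitosis genes had a median of 0.096 (adjusted p = 6.32e-05, and adjusted p = 0.692 with an estimated correlation). Beta cell genes had a median of 0.078, with Scg2 at 0.25 and Iapp at 0.15 (adjusted p = 0.00407, and adjusted p = 0.692 with an estimated correlation). DNA replication genes (0.041, adjusted p = 0.00407), ER chaperones (0.073, adjusted p = 0.00723), integrated stress response genes (−0.10, adjusted p = 0.00407) and hypoxia genes (−0.061, adjusted p = 0.0462) were also called, each with adjusted p = 0.692 with an estimated correlation. Without the array of 22.7 mM, 1 µM and 2 h the integrated stress response median was 0.019 and was not called. The proteasome score was higher in 6 of 6 pairs (exact permutation p = 0.0312, adjusted p = 0.624). In the same 6 pairs the Gapdh 3′ minus 5′ signal was lower at 20 µM, by −0.206 on average. The actin signal moved both ways between these doses. At 24 h it went from 1.96 to 1.36 at 22.7 mM and from 0.987 to 1.29 at 5.5 mM.

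Single genes of smallest p were Snrpd3 (0.48), Ubxn1 (0.35), Alyref (0.33), Fkbp2 (0.31) and Bex2 (0.26) among higher ones. Among lower ones they were Shisa2 (−0.46), Hacd1 (−0.37), Ncoa6 (−0.32), Smoc1 (−0.28) and Rcbtb2 (−0.25). By limma 0 genes passed, with adjusted p of 0.998 or more and 176 at an unadjusted p under 0.05, and 0 passed without the 2 deviating arrays or with any other array left out. Ddit3, Hspa5, Ins2, Pdx1 and Txnip differed by −0.10 to 0.19, and of these all but Ins2 changed sign under some alternative processing.

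Between 10 and 1 µM the genes of smallest p were Jund (−0.49, SE 0.11), Spock2 (−0.63), Atn1 (−0.59), Ap2a1 (−0.45) and Btrc (−0.43), and Adh1 (0.34), Zfand2b (0.28), Ibtk (0.27), Tpx2 (0.27) and Cnbp (0.25). By limma 0 passed and 208 had an unadjusted p under 0.05, and 0 passed without the 2 deviating arrays. Mitosis genes had a median of 0.10, positive in 21 of 23 (camera adjusted p = 2.26e-05, and adjusted p = 0.598 with an estimated correlation), and immediate early genes one of −0.096 (adjusted p = 0.00757, and adjusted p = 0.598 with an estimated correlation). Proteasome (0.060, adjusted p = 0.0164) and integrated stress response genes (−0.088, adjusted p = 0.0191) were called too, both with adjusted p = 0.833 with an estimated correlation. Without that same array of 22.7 mM, 1 µM and 2 h the integrated stress response median turned to 0.072. Camera then called this list in the opposite direction (adjusted p = 0.0073), and the proteasome list (0.044) was not called.

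**Figure D5:**
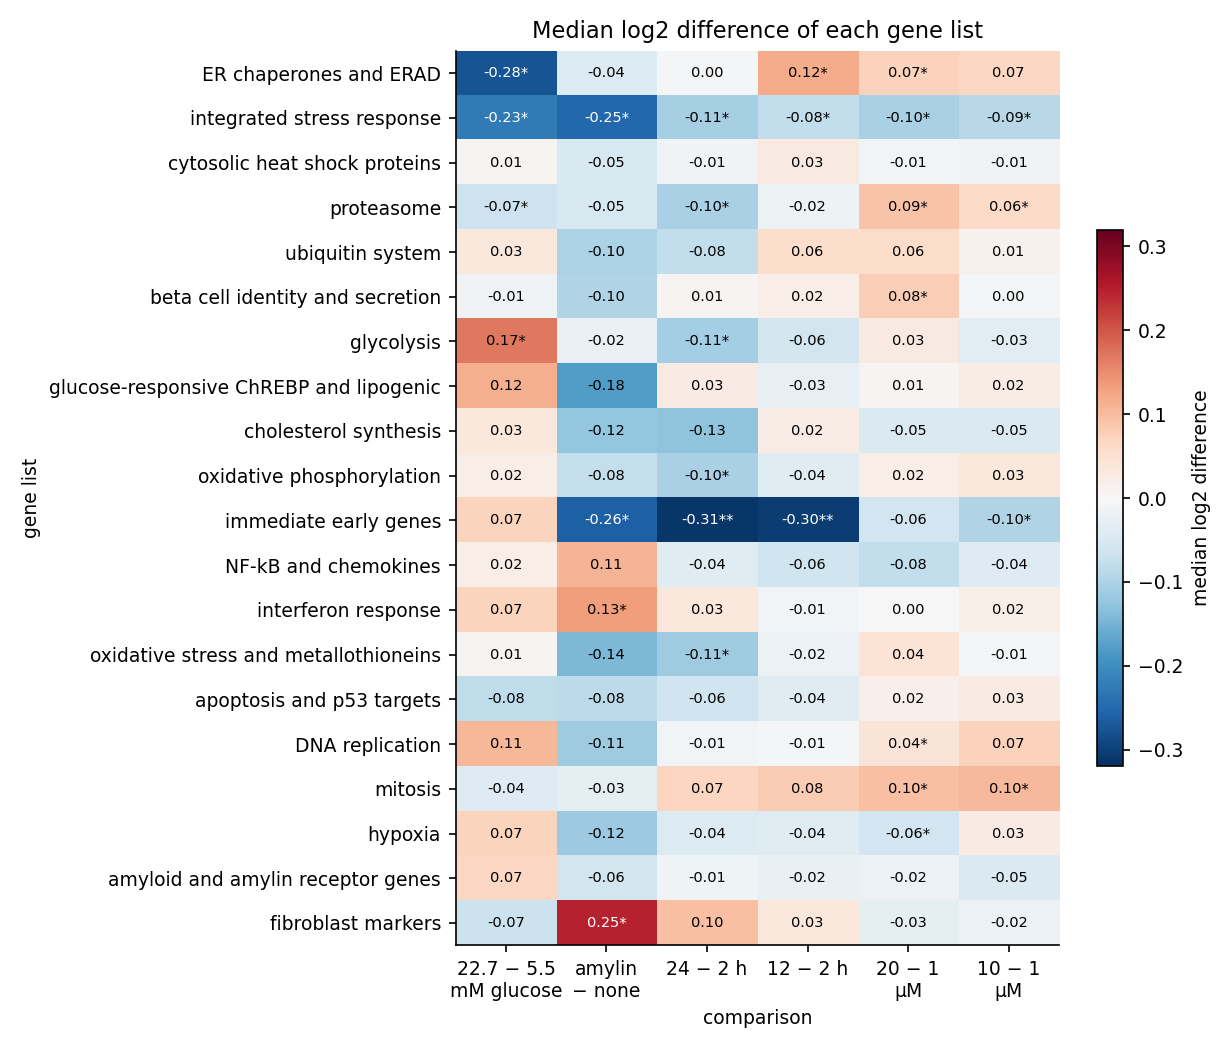
Median log2 difference of the tested members of 20 gene lists (vertical axis) in 6 comparisons (horizontal axis), coloured by value, with 1 star for a camera adjusted p under 0.05 at the preset correlation and a pair of stars where it also held with an estimated correlation. The immediate early list carries the pair at 24 minus 2 h (−0.31) and 12 minus 2 h (−0.30), and no called median changes sign when the arrays are centred or quantile normalized again.

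Whether glucose altered the response to amylin was tested as interactions. For the effect of amylin, Fos (−1.84, SE 0.40), Rgs2 (−0.94, SE 0.20), Tob1 (−0.94), Errfi1 (−0.87) and Desi2 (−0.71) were lower at 22.7 than at 5.5 mM, and Ppp4r3a (0.94), Tdp2 (0.87), Hspa1b (0.83), Fancg (0.82) and Invs (0.80) were higher, none passing. For the change from 2 to 24 h, Ddit3 differed by −1.04 (SE 0.27), Il4i1 by −0.77, Slc6a9 by −0.66, Mif4gd by −0.59 and Necap2 by −0.55, and Mns1 by 1.24, Cntn1 by 1.23, Tmem30a by 1.00, Yme1l1 by 0.87 and Pafah1b2 by 0.79. For the change from 1 to 20 µM, Endog (−0.93), Creld2 (−0.80), Gtf3c6 (−0.77), Cacng2 (−0.77) and Mpp6 (−0.72) were lower at 22.7 mM, and Dst (0.95), Supt20 (0.86), Ptbp2 (0.85), Tjp1 (0.83) and Pbrm1 (0.72) higher. By limma 0 genes passed in each interaction, with 281 (amylin), 799 (time) and 338 (dose) at an unadjusted p under 0.05 and smallest adjusted p of 0.999, 0.447 and 0.927. The change with dose at 24 h minus that at 2 h also gave 0 genes and 97 at an unadjusted p under 0.05. Its genes of smallest p were Sephs2 (1.24, SE 0.30), Pdcd4 (1.08), Sgtb (0.87), Cpq (0.71) and Tcf20 (0.62), and Fkbp11 (−1.09, SE 0.29), Khdc4 (−0.79), Nucb1 (−0.76), Htra2 (−0.73) and Cd151 (−0.71). Without the 2 deviating arrays all 4 counts were 0.

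Values at single times were not tested. Each is a mean over 3 doses of list medians against the 1 untreated array of the same glucose level. At 22.7 mM the immediate early median was −0.28 (SD 0.11 over 3 doses) at 2 h, −0.41 (SD 0.10) at 12 h and −0.44 (SD 0.08) at 24 h. At 5.5 mM it was 0.13 (SD 0.22), −0.21 (SD 0.11) and −0.31 (SD 0.34). The integrated stress response median at 5.5 mM was −0.49 (SD 0.23), −0.42 (SD 0.09) and −0.38 (SD 0.31) at these times, and at 22.7 mM it was 0.11 (SD 0.28), −0.09 (SD 0.11) and −0.14 (SD 0.16). Of the 3 doses behind the 0.11, 1 µM gave 0.43, 10 µM 0.01 and 20 µM −0.12. ER chaperone medians lay between −0.22 and 0.04 at 5.5 mM and between −0.09 and 0.02 at 22.7 mM. Heat shock medians were −0.12, −0.07 and −0.30 at 5.5 mM and −0.04, 0.02 and 0.13 at 22.7 mM. Proteasome medians were 0.08, 0.06 and −0.12 at 5.5 mM and −0.12, −0.09 and −0.09 at 22.7 mM. With the arrays centred on their medians, the proteasome values at 5.5 mM were 0.201 at 2 h and 0.021 at 24 h, and the heat shock value at 12 h was 0.047. The array of 5.5 mM, 10 µM and 24 h, 1 of the 2 deviating arrays, enters the 24 h values at 5.5 mM, and that of 22.7 mM, 1 µM and 12 h those of 12 h at 22.7 mM.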

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

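The test of RNA degradation in the 2 arrays without a scanner description was chosen only after its result was seen, as was the rule by which the test of a compressed range decides nothing, and scan day in the additive model, the 3′ minus 5′ signal as a term, and gene lists without those 2 arrays, without the array of 22.7 mM, 1 µM and 2 h or with scan day as a block were added after the data were seen.

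In each glucose level, array measures, list scores and the always-considered genes were searched for an array far from the other 9. An array stood far from the rest in 21 of 66 groups, where chance marks about 1 in 20 groups (3.3 of 66). Most belong to the 2 arrays without a scanner description. The array of 22.7 mM glucose with 1 µM amylin for 12 h had the highest median (7.25, others 7.04 to 7.12) and the lowest mean correlation (0.941, others 0.970 to 0.978). It also had low scores for beta cell genes (−0.233) and for ChREBP and lipogenic genes (−0.267). The array of 5.5 mM glucose with 10 µM amylin for 24 h had a median of 7.28 (others 7.08 to 7.15) and a mean correlation of 0.920 (others 0.969 to 0.977). Its scores were low for heat shock proteins (−0.352), the proteasome (−0.249), the ubiquitin system (−0.406), beta cell genes (−0.316), cholesterol synthesis (−0.479), oxidative phosphorylation (−0.241), oxidative stress (−0.343) and DNA replication (−0.373), and high for fibroblast markers (0.560). Hspa5 was 11.51 in it on the log2 scale, against 12.24 to 12.78 in the others. The spiked Cre control was 10.79 and 10.40 in these 2 arrays (10.80 to 12.91 in the other 18). In the array at 5.5 mM the BioB control (6.53) and the 18S signal (8.74) were also below the lowest of the 18 (6.61 and 9.57).

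Other arrays stood apart in single measures. At 5.5 mM glucose, the actin 3′ minus 5′ signal was 1.77 with 10 µM for 12 h (others 0.978 to 1.40), the BioB control was 8.84 with 20 µM for 24 h (others 6.53 to 7.72), and Txnip was 8.76 with 1 µM for 2 h (others 7.20 to 7.87). At 22.7 mM with 1 µM for 2 h, the integrated stress response score was 0.352 (others −0.375 to −0.057) and Ddit3 was 9.58 (others 8.32 to 8.72).

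In the 4 interaction tests, camera made 17 calls over 11 different lists at the preset correlation, and none with an estimated correlation. The effect of amylin differed between 22.7 and 5.5 mM glucose by a median of 0.37 for the integrated stress response (adjusted p = 0.00385), −0.18 for the proteasome (adjusted p = 0.00112) and −0.19 for immediate early genes (adjusted p = 3.62e-04). With an estimated correlation the adjusted p was 0.814, 0.814 and 0.257. With scan day as a block none of these was called, and the medians were 0.35, −0.11 and −0.016. All 3 rest on 1 untreated array per glucose level, of which that at 5.5 mM had the highest integrated stress response score of all arrays (0.51) and that at 22.7 mM the highest immediate early score (0.46). The change from 2 to 24 h differed by −0.42 for the integrated stress response (adjusted p = 2.62e-05), 0.29 for the proteasome, 0.24 for ubiquitin, 0.18 for oxidative phosphorylation, −0.25 for NF-kB, −0.12 for interferon, 0.24 for DNA replication, 0.22 for mitosis and −0.27 for fibroblast markers. With an estimated correlation these had adjusted p of 0.193 to 0.584. Without the 2 deviating arrays 5 of these 9 lists were called, and oxidative phosphorylation (0.12), interferon (−0.14), DNA replication (0.062) and fibroblast markers (−0.043) were not. With scan day as a block the interferon (−0.098, camera adjusted p = 0.161) and fibroblast (−0.051, adjusted p = 0.312) lists were not called. Glycolysis (0.44, adjusted p = 0.00114) and ER chaperones (−0.089, adjusted p = 0.0109, against 0.14 in the main fit) were called besides. Leaving out the array of 22.7 mM, 1 µM and 2 h, which stands apart in the integrated stress response, changed that list from −0.42 to −0.17 and ended the calls of oxidative phosphorylation (0.10) and interferon (−0.14), and the fibroblast median was −0.50. The change from 1 to 20 µM differed by −0.12 for ER chaperones and −0.25 for the integrated stress response (adjusted p = 0.0163 and 7.3e-04, both 0.656 with an estimated correlation). With scan day as a block these medians were −0.41 and −0.79. Every fit with scan day as a block also leaves out the 2 deviating arrays, so this change cannot be credited to scan day alone. Without the array of 22.7 mM, 1 µM and 2 h they were −0.02 and −0.14, and neither was called (adjusted p = 0.171 for both). The change with dose at 24 h minus that at 2 h was −0.17 for the integrated stress response, 0.25 for immediate early genes and 0.10 for mitosis (adjusted p = 0.0149, 0.0149 and 0.0291, all 0.917 with an estimated correlation). These were −0.38, 0.31 and 0.13 with scan day as a block, and ER chaperones (−0.19) were called besides. Without that same array the medians of the first 3 lists were −0.57, 0.58 and 0.18.

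The first pattern weighed is the lower expression of ER chaperone and integrated stress response genes at 22.7 mM glucose. Scan day alone is argued against, because with it as a term the score differences were −0.232 (SE 0.0519) and −0.341 (SE 0.117). The 2 deviating arrays are argued against as the cause, because without them the differences were −0.243 (SE 0.0504) and −0.297 (SE 0.121). RNA quality and glucose cannot be told apart here, because the 3′ minus 5′ signal was higher at 22.7 mM in all 10 pairs. Extrapolated to pairs of equal signal, the differences were −0.070 (SE 0.121) and −0.200 (SE 0.199), and −0.163 (SE 0.108) and −0.291 (SE 0.175) in an additive model with the signal as a term, all within 2 SE of 0, so RNA quality and glucose both remain open.

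The second pattern is that the 2 arrays without a scanner description stand apart. Degraded RNA stays open. Actin shows no sign of it: the higher of their actin 3′ minus 5′ signals was 1.66, inside the range of the other 18, which reached 2.60. That range pools both glucose levels, which differ in this signal. The Gapdh 3′ minus 5′ signal was 1.21 in the array at 5.5 mM, above the highest other array at that level (1.16). In the array at 22.7 mM it was 1.56, below the highest at that level (1.78). A compressed range of values stays open: quantile normalization moved the higher of their mean correlations with the other 18 only from 0.941 to 0.939, so its distance from the lowest of the 18 (0.973) decides nothing, and in both arrays the genes of lowest mean were raised and those of highest mean lowered. RNA from fibroblasts stays open: the median deviation of 5 fibroblast markers lay at percentile 99.13 of random lists in the array at 5.5 mM and at 95.01 in that at 22.7 mM. Other listed fibroblast markers, among them Col1a1 and Vim, lay below the expression filter and do not enter this value. Acinar markers were raised and the Cre control was low in both arrays too, a separate run or hybridization was not tested, and no biological explanation was tested.

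The third pattern is the lower expression of immediate early genes at 24 than at 2 h of amylin. Scan day is argued against, because with it as a term the score difference was −0.427 (SE 0.0989), against −0.341 in the same 18 arrays without the term. The 2 deviating arrays are argued against by a difference of −0.336 (SE 0.0805) without them, and RNA quality by one of −0.395 (SE 0.0915) with the 3′ minus 5′ signal as a term. A response to amylin that fades with time and handling of the cells, such as a change of medium, stay open as hypotheses found and tested on the same data, since no untreated array was paired with each time. Against the untreated array, the 2 h median was −0.28 (SD 0.11 over doses) at 22.7 mM and 0.13 (SD 0.22) at 5.5 mM. Each level had a single untreated array, and that at 22.7 mM had the highest immediate early score of all arrays (0.46). The time at which untreated cells were collected was not given. The SD leaves out the uncertainty of the untreated array, so these values do not decide whether a rise came before the fall.

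The labels of the compared groups were swapped within matched pairs to see how many genes other arrangements of the arrays give. For glucose, 1 of 100 arrangements (the real one) gave as many as 408 genes and the highest other gave 216, which argues against chance. That other arrangement had 2 pairs swapped, which leaves most of the real difference in place. For 24 minus 2 h, only 1 of 32 arrangements gave as many as 4 genes (highest other 0), and for 12 minus 2 h only 1 of 32 gave as many as 8 (highest other 1). This is the smallest share that 32 arrangements can give. It is under 0.05 for each comparison alone but was not adjusted over the comparisons, so chance is not excluded for either. The 4 genes fell to 0 with the arrays centred. For 20 minus 1 µM and for 10 minus 1 µM the real count was 0 (highest other 0), which all 32 arrangements reach by construction, so there is no result for chance to explain. For the differences between glucose levels in the change with time and with dose, where glucose labels were swapped, all 100 likewise reach the real 0. Their highest others of 14 and 21 came with 4 and 5 of the 10 pairs swapped. Such swaps carry the glucose difference into these terms, so these counts do not separate glucose from other structure of the arrays.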

How the results depend on the processing

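Array weights, the RNA quality covariate (3′ minus 5′ signal), scan day in the additive model, and the gene lists without the 2 undescribed arrays or the array of 22.7 mM, 1 µM and 2 h or with scan day as a block were chosen after seeing the data. The cause of a change was not tested unless given. Fits with scan day also left out the 2 undescribed arrays.

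For glucose (408 genes), 9 of 14 alternatives stayed within 1.5 times, from 296 (no filter, 254 shared) to 437 (quantile normalization, 348 shared). The count was 743 without the 2 undescribed arrays (387 shared), 1090 with scan day as a block (373 shared), 1150 with array weights, 28 with an absolute log2 difference of at least 0.58, and 0 with the covariate. With the covariate the median absolute difference of the 408 genes went from 0.333 to 0.316 and their median SE from 0.0777 to 0.142, as the signal moves with glucose. List score differences moved both ways. That of ER chaperones went from −0.212 to −0.070 (SE 0.121) and that of glycolysis from 0.202 to 0.317 (SE 0.152). The lost calls therefore do not tell RNA quality from glucose. Leaving out 1 array gave 98 to 657, and either array of a pair removes the whole pair. Counts that moved by more than 1.5 times were 145 without 1 µM 24 h (either glucose level), 98 and 113 (22.7 and 5.5 mM) without 10 µM 2 h, 135 without 10 µM 12 h, 657 and 656 without 10 µM 24 h, 180 without 20 µM 2 h, 99 without 20 µM 12 h and 204 without 20 µM 24 h.

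For 24 minus 2 h (4 genes) 7 of 14 alternatives stayed within 1.5 times. The count was 0 with the arrays centred, 14 with robust estimation, 33 without the 2 arrays, 9 with scan day as a block (1 shared), 1 with the covariate, and 13 with the additive model or the 18 treated arrays alone. Leaving out 1 array gave 0 to 143. At 22.7 mM it was 143 without 10 µM 24 h, 20 without 1 µM 12 h, 13 without the untreated array, 8 without 1 µM 2 h, and 0 without 1 µM 24 h, 10 µM 2 h, 20 µM 2 h or 20 µM 24 h. At 5.5 mM it was 20 without 1 µM 12 h, 13 without the untreated array, 10 without 10 µM 24 h, 2 without 20 µM 2 h and 0 without 1 µM 24 h.

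For 12 minus 2 h (8 genes) the count was 55 without the 2 arrays, 26 with array weights, 84 with scan day in the additive model (7 shared), 21 with the additive model and 15 with the 18 treated arrays alone. Leaving out 1 array gave 4 to 39. At 22.7 mM it was 39 without 10 µM 24 h, 16 without 1 µM 2 h, 15 without the untreated array, 5 without 10 µM 2 h or 10 µM 12 h, and 4 without 20 µM 2 h or 20 µM 12 h. At 5.5 mM it was 39 without 10 µM 24 h, 29 without 1 µM 12 h, 15 without the untreated array and 5 without 10 µM 12 h.

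Amylin minus none gave 1 gene with the 12 h arrays only and 0 to 1 with an array left out (1 without 5.5 mM 20 µM 24 h). For 10 minus 1 µM the range was 0 to 1 (1 without 22.7 mM 10 µM 2 h), and 20 minus 1 µM and dose by time stayed at 0. Glucose by amylin gave 193 and glucose by time 92 with array weights, whose estimation did not converge. Scan day as a block gave 6 for glucose by time and 6 for glucose by dose. With an array left out, glucose by time gave 0 to 2 (2 without 22.7 mM 1 µM 2 h). Scan day as a block could not be fitted for amylin, 12 minus 2 h, 20 minus 1 and 10 minus 1 µM, nor could glucose by amylin without an untreated array. Fits within a glucose level gave gene values with no test.

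With an estimated correlation and with fry, the number of called lists fell to 0 in each comparison, except for 1 at 24 minus 2 h and 1 at 12 minus 2 h. Without the 2 arrays there were 3 lists at 24 minus 2 h (main 6), 6 at 12 minus 2 h (main 3) and 5 for glucose by time (main 9). With scan day as a block there were 3 at 24 minus 2 h, 0 for glucose by amylin (main 3) and 5 for glucose by dose (main 2). With no filter there were 10 for amylin (main 4), 6 at 12 minus 2 h and 4 for glucose by dose, and with the mean of probe sets 4 for 20 minus 1 µM (main 7). Without the array of 22.7 mM, 1 µM and 2 h there were 5 lists at 12 minus 2 h, 5 for dose by time (main 3) and 0 for glucose by dose. Of 295 list alternatives 128 lost the call and 5 turned upward: glycolysis at 24 minus 2 h with scan day as a block (0.143), and without that array the integrated stress response at 24 minus 2 h (0.020), 12 minus 2 h (0.058), 20 minus 1 µM (0.019) and 10 minus 1 µM (0.072). Of these 5 only the last was called upward by camera (adjusted p = 0.0073).

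Of 5925 alternatives for 179 named gene values, 451 lost the call, 113 gained one and 47 changed sign. For glucose these were Glp1r (0.091, SE 0.143), Uba3 (0.050, SE 0.155) and Hspa5 (0.063, SE 0.227) with the covariate and Pdx1 with the mean of probe sets (−0.093). The rest were uncalled values near 0. Without the 2 arrays, Ddit3 (−0.071) and Hspa5 (0.095) turned at 24 minus 2 h, and Hspa5 (−0.036) and Pdx1 (−0.063) at 20 minus 1 µM. With scan day as a block at 24 minus 2 h, Ddit3 (−0.327), Hspa5 (0.081) and Iapp (−0.031) turned. Quantile normalization turned Iapp (−0.018) and Txnip (−0.011) there and Pdx1 at 20 minus 1 µM (−0.029), and centring turned Iapp (−0.011), Ins2 (−0.012) and Txnip (−0.020) at 24 minus 2 h. The covariate turned Txnip at 24 minus 2 h (−0.053), Hspa5 (−0.057) and Pdx1 (−6.7e-04) at 20 minus 1 µM, and scan day in the additive model Pdx1 (−0.100) and Txnip (−0.074) there. With an array left out, the ranges at 24 minus 2 h were −0.254 to 0.322 (Ddit3), −0.361 to 0.108 (Hspa5), −0.011 to 0.047 (Iapp), −0.0013 to 0.035 (Ins2) and −0.434 to 0.452 (Txnip). At 20 minus 1 µM they were −0.393 to 0.183 (Ddit3), −0.060 to 0.237 (Hspa5), −0.064 to 0.105 (Pdx1) and −0.255 to 0.631 (Txnip), and for amylin −0.095 to 0.061 (Ins2).

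Centring the arrays moved single-condition medians at 5.5 mM to −0.097 (immediate early, 12 h), 0.159 (ER chaperones, 12 h), −0.302 (integrated stress response, 12 h), 0.201 and 0.021 (proteasome, 2 and 24 h), and −7.4e-04 and 0.047 (heat shock, 2 and 12 h). At 22.7 mM it moved ER chaperones at 2 h to −0.048. In the 10 comparisons centring shifted the median of all genes by at most 0.091.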

Other observations

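Signals of different genes are not ranked here, since each comes from its own probe set. Ins2 averaged 14.60 (SD 0.06) at 22.7 mM and 14.69 (SD 0.05) at 5.5 mM on the log2 scale, Iapp 13.72 and 13.83, and Chga, which encodes the granule protein chromogranin A and was chosen after its values were seen, 13.48 and 13.49. Gcg, the glucagon gene, averaged 11.13 and 11.32, Pdx1 11.12 and 10.99, and Sst 7.28 and 7.92.

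In the 2 arrays without a scanner description, the 1488 genes of lowest mean expression were raised by 0.22 (22.7 mM) and 0.27 (5.5 mM), and the 1487 of highest mean expression differed by −0.20 and −0.32 from their means. Acinar markers deviated by 0.44 and 0.57 (2 genes), other islet hormone genes by 0.32 and 0.45 (3 genes), and duct markers by −0.24 and −0.15 (4 genes).

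Within each glucose level the ER chaperone and integrated stress response scores were also set against the mean 3′ minus 5′ signal over 10 arrays, 4 relations in all. For ER chaperones r was −0.280 (permutation p = 0.433) and rho −0.188 (permutation p = 0.607) at 22.7 mM, and r 0.105 (permutation p = 0.759) and rho 0.006 (permutation p = 1) at 5.5 mM. For the integrated stress response r was 0.354 (permutation p = 0.314) and rho 0.673 (permutation p = 0.0393, adjusted p = 0.157) at 22.7 mM, and r 0.0926 (permutation p = 0.801) and rho 0.224 (permutation p = 0.534) at 5.5 mM. All adjusted p were 0.157 or more. Without the 2 arrays farthest from the median signal, r was −0.199, −0.053, 0.411 and 0.158 in the same order.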
